A study of Arabidopsis thaliana with 12 samples.

How the data were processed

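Transcript levels were measured in leaves of Arabidopsis thaliana on the Affymetrix ATH1 array, which carries 1 probe set per transcript or small group of transcripts. The series held 12 arrays from 4 genotypes, with 3 arrays per genotype. The genotypes were wild type Columbia, sex1-3, sex4-3 and ptpkis2; the labels give sex4-3 and ptpkis2 as Salk insertion lines and sex1-3 as an induced mutation in the Columbia background. Per the labels, the plants grew with 12 hours of light per day at 100 micromol m-2 s-1 and 20 degrees Celsius, 8 plants of each genotype gave 3 leaves, and leaves were taken in the dark, 0.5 hours before the day began. The labels do not state whether the 3 arrays of a genotype came from separate plants or pools, so the p-values measure only the spread between these arrays, which may be technical.

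Per the submitters' processing notes, MAS5 and GCOS made the values, and their versions are not given in the sources used here. The deposited table gave 1 signal intensity per probe set and array, on a linear scale and above 0 throughout. The trimmed mean lay between 99 and 99.3 on every array, so the authors had scaled the arrays to a common level, and the target value is not given in the sources used here. Detection calls were not used here, and the number of arrays limits the precision of every value.

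From these signals, log2 values were taken with no pseudocount and no further normalization. Of the 22810 probe sets, 64 Affymetrix control probe sets were left out of the tests, as were the 40% of the others with the lowest mean log2 signal, which left 13647. One linear model per probe set over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal, 8 residual degrees of freedom). It gave 6 comparisons between genotypes and a moderated F-test for any difference of a mutant from wild type. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p below 0.05. Each fold change is given as log2 ± its standard error (SE).

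Probe sets were named from the platform annotation, with symbols updated through a RefSeq table of assembly TAIR10.1 that served for names only. Apart from the controls, 13513 probe sets paired with 1 gene, 503 with several genes, and 8730 are unnamed here. The RefSeq table held 13436 of the first kind, and 1580 had a symbol other than a locus number. No probe set was named SEX1, SEX4 or LSF1 in these tables, so the mutated genes' own transcripts were not identified and the labels were not checked by them, although probe sets unnamed here, which were kept in the tests, may include them.

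Before the data were examined, the comparisons, the tests, 21 gene lists with 306 genes, the other analysis settings and the rule for named genes were fixed. The rule took, for each mutant against wild type, up to 10 called genes with the largest rise and 10 with the largest fall whose 3 mutant values all lay on one side of the 3 wild type values, up to 4 called members of each fixed list, and every measured member of the starch degradation list. Between mutants it took 5 in each direction. Only 43 genes of the fixed lists had a named probe set, and 2 lists, carbon starvation and light harvesting, had the 5 kept members that a test required. Therefore 22 lists were added from names, loci or chromosomes in the annotation, and 21 of them could be tested. They were written after the counts of calls had been seen and after wild type replicate 2 had been compared with the other arrays, when its high plastid transcripts were known, but before any gene's fold change between genotypes was looked at. The loci of the ribosomal protein list were written from memory. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, with 1 probe set per gene; the fixed lists formed 1 family of tests over the 3 mutant comparisons and the added lists another.

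Correlations between arrays, spike-in signals and 3′ to 5′ ratios of the control probe sets were compared before testing. Wild type replicate 2 stood apart, so each count was computed again without it, with the filter taken from the other 11 arrays, an alternative chosen after seeing the data along with array weights. The settings fixed beforehand were quantile normalization, median centring of each array, other filters on low signal, a floor and a pseudocount at the 20th percentile, eBayes without a trend or in its robust form, fits of the 2 genotypes compared alone, the replicate number as a block, and leaving out each array in turn.

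The fit was tested on simulated data for sex1-3 minus wild type over 13647 probe sets in 20 draws. With 12 arrays, 1 noisier than wild type replicate 2, it recovered on average 10.1% of 2-fold and 58.2% of 4-fold changes. On average 1.41% of its calls were false. With 11 arrays these values were 42.6%, 84.8% and 5%. The noisy array held simulated noise plus the real deviations of replicate 2, shuffled over probe sets. In the data chloroplast transcripts were high together on that array, so the 12-array values only approximate the data. For the 8 members of the carbon starvation list, a simulated shift of 1 on the log2 scale was called in 20 of 20 draws in both settings and no shift in 0 of 20. The simulated genes varied independently of one another, so these draws do not test the list with correlated members. In the data the estimated correlation of its members was 0.03 with 12 arrays and 0.15 without wild type replicate 2.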

Results

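Leaf transcripts at the end of the night were compared between wild type Columbia and 3 mutants impaired in starch breakdown. Glucan, water dikinase (SEX1), which phosphorylates starch, is affected in sex1-3. The phosphoglucan phosphatase SEX4 is affected in sex4-3, and ptpkis2 affects PTPKIS2, a related protein also known as LSF1. Each genotype had 3 arrays. The median signal lay between 24 and 29.7 on 11 arrays and was 62.2 on wild type replicate 2.

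Wild type replicate 2 correlated with the other arrays at r = 0.586 to 0.604 across probe sets, whereas the other 11 arrays correlated with one another at 0.891 to 0.93. The median correlation of those 11 was 0.918 within a genotype and 0.912 between genotypes. The 18 spike-in probe sets had a median ratio of 23.3 to the other arrays on wild type replicate 2, against 0.525 to 1.34 on the others. Transcripts of the chloroplast genome made up 8.83% of its signal, against 2.58 to 4.09% on the other arrays. No pair of replicate arrays held identical values. Values without wild type replicate 2 are therefore given beside the counts from all 12 arrays.

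**Figure D1:**
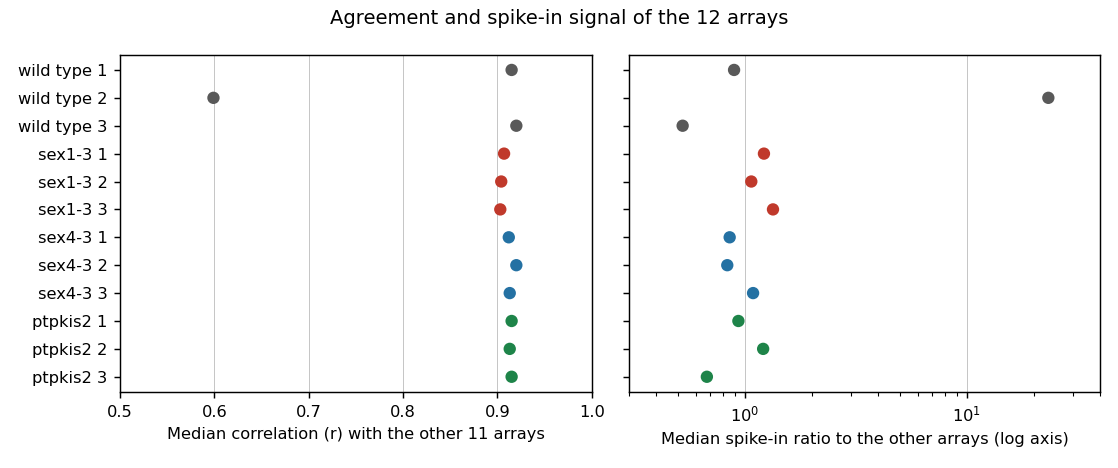
Median correlation of each array's log2 signals with the other 11 arrays (left, Pearson's r across probe sets) and median signal of the spike-in probe sets relative to the other arrays (right, ratio on a log axis), 1 point per array, coloured by genotype. Wild type replicate 2 lay at 0.599 and 23.3, apart from the other 11 arrays.

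The comparison of sex1-3 with wild type asked which transcripts differ when starch phosphorylation is impaired. The named genes IVD, MCCA, MGL and AKINBETA1 rose in sex1-3. IVD (AT3G45300), isovaleryl-CoA dehydrogenase of leucine breakdown, was 8.4-fold higher in sex1-3 (log2 3.07 ± 0.48, n = 3 per genotype, adjusted p = 0.0057). MCCA (AT1G03090), a subunit of methylcrotonyl-CoA carboxylase in the same pathway, was 2.94-fold higher (1.56 ± 0.21, adjusted p = 0.0025). AKINBETA1 (AT5G21170), a regulatory subunit of the energy-sensing kinase SnRK1, rose from a mean signal of 450 ± 29.3 to 1220 ± 48.9 (SD, n = 3), which was 2.7-fold (adjusted p = 0.00041). MGL (AT1G64660), methionine gamma-lyase, was 9.66-fold higher (3.27 ± 0.51, adjusted p = 0.0061).

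Among the largest falls of named genes in sex1-3, CHIL (AT5G05270), a chalcone isomerase-like protein of flavonoid synthesis, fell by 4.38 ± 0.72 on the log2 scale (adjusted p = 0.0081), and GH9B8 (AT2G32990), a member of the glycosyl hydrolase 9 family, fell by 3.54 ± 0.75 (adjusted p = 0.029). AT1G73600 fell from a mean signal of 178 ± 78.1 to 8.02 ± 3.81 (log2 -4.46 ± 0.40, adjusted p = 0.00039). The other 7 of the 10 largest falls of named genes were loci without a symbol, from AT5G22460 (-4.80 ± 0.73) to AT5G48490 (-3.06 ± 0.30), and 2 probe sets unnamed here had values of -6.04 ± 0.69 and -4.84 ± 0.73 (-5.70 and -4.22 without wild type replicate 2). Some of these values rest on signals near background in sex1-3, so their size is uncertain: AT5G22460 had a mean of 1.84 ± 0.965 and GH9B8 of 2.28 ± 1.14, below the 20th percentile of the sex1-3 arrays (2.78 to 3.19), and CHIL had 1.13, 1.69 and 11.9. With signals below the 20th percentile of all arrays raised to it, AT5G22460 fell by 3.48, CHIL fell by 3.31, AT1G13650 fell by 3.55, the 2 unnamed probe sets had -4.04 and -3.37, and GH9B8 had a value of -2.55 that no longer passed. Of the largest rises, CCOAMT (AT1G67980), caffeoyl-CoA 3-O-methyltransferase of phenylpropanoid metabolism, was at 3.32 ± 0.76 (adjusted p = 0.042). Of the named genes AT5G57655 rose most with 12 arrays (3.62 ± 0.82, adjusted p = 0.04), below 2 probe sets unnamed here (4.58 ± 0.52 and 3.76 ± 0.65, or 5.25 and 2.90 without wild type replicate 2). Without wild type replicate 2 its value was 2.32. AT2G05540 (3.11), AT1G72060 (2.84), MGL (2.62), AT1G66760 (2.55), AT1G05340 (2.49), AT1G75200 (2.39) and IVD (2.36) then lay above it. Another 6 loci without a symbol rose by 2.38 (AT1G75200) to 2.98 (AT2G05540).

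The fixed carbon starvation list, genes known to rise when sugars run out, rose as a group in sex1-3. Only 8 of its 30 genes had a named probe set, among them IVD and MCCA of leucine breakdown, so the result covers these members and not the whole list. All 8 measured members had values above 0, with a median of 1.31. Of these, 3 rose over all genes tested (IVD, MCCA and AKINBETA1), or 4 when adjusted over the list alone. The list passed camera at an adjusted p of 2e-05 and, with an estimated correlation, at an adjusted p of 0.014. Its camera adjusted p ranged from 2.7e-08 to 9e-04 over all alternatives. AT4G33150, listed as LKR of lysine breakdown, had a value of 1.71 ± 0.50 (adjusted p = 0.095), and ETFQO, D2HGDH, MCCB and ATG8E had 0.10, 0.01, 1.19 and 0.71 without passing. Leaving out wild type replicate 2 gave 1.15, 0.99, 0.19, 0.33 and 0.19 for these 5 genes, of which ETFQO then passed. The light harvesting list had 0 of 5 members past the threshold (median -0.21, mean -0.04, adjusted p = 0.99), with a median of 0.08 without wild type replicate 2. No kept member of the other fixed lists passed in any comparison of a mutant with wild type. The starch degradation genes PWD (-0.29 ± 0.21), DPE1 (-1.33 ± 0.58) and AMY1 (-0.77 ± 0.70) did not pass (adjusted p = 0.42, 0.24 and 0.51), and without wild type replicate 2 they were at -0.28, -0.59 and -0.05.

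In all, limma called 403 of 13647 probe sets between sex1-3 and wild type, 148 higher and 255 lower in sex1-3, and in each of them the 3 sex1-3 signals all lay above or all below the 3 wild type signals. Such separation held for 22.6% of all tested probe sets, where chance gives 10%. The count was 1211 without wild type replicate 2, which included all 403, 806 without wild type replicate 3, and 157 to 189 without 1 of the sex1-3 arrays. Without wild type replicate 2 the rises of IVD, MGL, CCOAMT, AT5G57655 and AT5G19120 were 2.36, 2.62, 2.18, 2.32 and 1.68, where all 12 arrays gave 3.07, 3.27, 3.32, 3.62 and 2.66, and the falls of AT5G22460 and GH9B8 were -3.88 and -2.52.

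**Figure D2:**
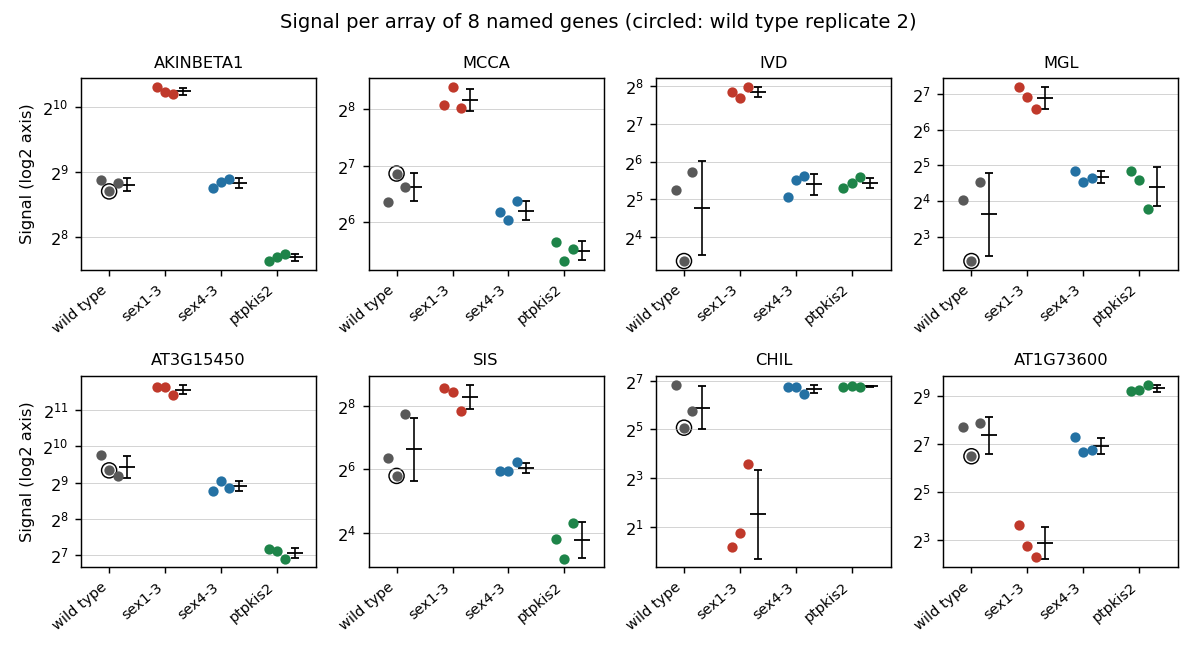
Signal of 8 named genes on each array (log2 axis, 1 point per array, coloured by genotype), with the mean and SD of the 3 log2 signals as bars and wild type replicate 2 circled. AKINBETA1 lay at 1180 to 1270 in sex1-3, 418 to 474 in wild type and 199 to 215 in ptpkis2.

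The comparison of sex4-3 with wild type asked the same for loss of the phosphatase SEX4. No named gene passed the threshold. The starch degradation genes PWD (-0.39 ± 0.21), DPE1 (-0.71 ± 0.58) and AMY1 (-1.08 ± 0.70) had adjusted p of 0.57, 0.58 and 0.57 (n = 3 per genotype), with values of -0.38, 0.03 and -0.37 without wild type replicate 2. The carbon starvation list had a median of 0.17 with 0 of 8 members past the threshold (adjusted p = 0.99), or -0.06 without wild type replicate 2, and the light harvesting list had a median of 0.10 with 0 of 5 (adjusted p = 0.99). AKINBETA1 lay between 432 and 477 on the 3 sex4-3 arrays, where wild type had 418 to 474. The 1 probe set called is unnamed here and fell from a mean signal of 89.5 ± 21.7 to 9.03 ± 1.43 (log2 -3.29 ± 0.27, adjusted p = 0.00083). Its signal on the sex1-3 and ptpkis2 arrays was 67.2 to 101 and 81.5 to 90.5. At an unadjusted p below 0.05, limma gave 714 probe sets, where chance gives 682, and the 3 against 3 signals did not overlap in 8.54% of probe sets, where chance gives 10%. The call was again that probe set without wild type replicate 2, and the unadjusted count was 639. With array weights, chosen after seeing the data, limma called 24 probe sets, 17 higher and 7 lower in sex4-3.

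The comparison of ptpkis2 with wild type asked the same for PTPKIS2. Here AKINBETA1 fell: its mean signal was 207 ± 8.19 in ptpkis2 and 450 ± 29.3 in wild type (log2 -1.12 ± 0.14, n = 3 per genotype, adjusted p = 0.0064). SIS (AT5G02020), named for salt-induced expression, fell by 2.86 ± 0.45 (adjusted p = 0.036), and the locus AT3G15450 was 5.13-fold lower (-2.36 ± 0.18, adjusted p = 0.00036). AT2G20670 and AT4G27450 fell by 2.19 ± 0.23 and 2.17 ± 0.31, and 6 further loci without a symbol by 1.12 (AT4G17245) to 1.81 (AT1G78450). TBL26 (AT4G01080), of a family that acetylates wall polysaccharides, rose 3.41-fold (1.77 ± 0.30, adjusted p = 0.042), and AT5G02870, a member of the added ribosomal protein list, rose by 0.96 ± 0.16 (adjusted p = 0.039).

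Of the carbon starvation list, 1 of 8 members fell in ptpkis2, or 2 when adjusted over the list alone. The list as a group did not pass camera (median -0.18, adjusted p = 0.096, or adjusted p = 0.23 with an estimated correlation) but passed fry, which asks whether its genes moved one way on balance (adjusted p = 0.028). Its median turned to 0.12 under median centring of the arrays, which also moved the median of all tested probe sets from 0.05 to 0.36. MCCA had a value of -1.13 ± 0.21 (adjusted p = 0.057) and IVD of 0.67 ± 0.48 (adjusted p = 0.5), and without wild type replicate 2 they were at -1.01, which passed, and -0.04. The light harvesting list had a median of 0.00 and 0 of 5 members past the threshold (adjusted p = 0.99). PWD (-0.05 ± 0.21), DPE1 (-0.80 ± 0.58) and AMY1 (-0.74 ± 0.70) did not pass (adjusted p = 0.9, 0.51 and 0.59), and were at -0.04, -0.06 and -0.02 without wild type replicate 2.

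In all, limma called 36 probe sets between ptpkis2 and wild type, 10 higher and 26 lower in ptpkis2, all with non-overlapping signals, which held for 17.8% of all tested probe sets. The count was 369 without wild type replicate 2, which included all 36, and 6 to 9 without 1 of the ptpkis2 arrays. Without wild type replicate 2 the carbon starvation list had 3 of 8 members lower and an adjusted p of 0.011, in a range of 0.0094 to 0.55 over all alternatives, with an adjusted p of 0.22 with an estimated correlation.

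**Figure D3:**
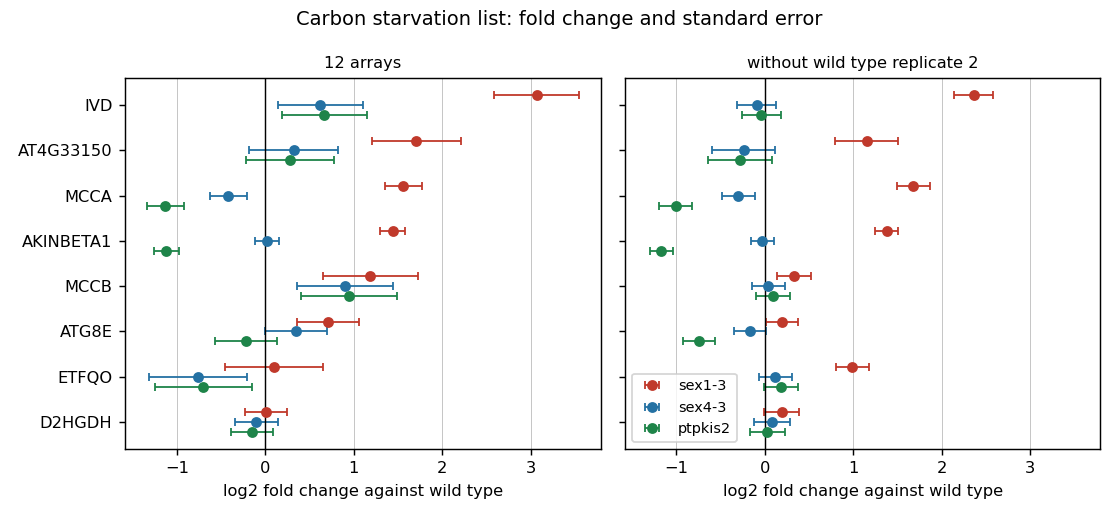
Log2 fold change against wild type with its standard error for the 8 measured members of the carbon starvation list, for sex1-3, sex4-3 and ptpkis2 (n = 3 arrays per genotype), from all 12 arrays (left) and without wild type replicate 2 (right). In sex1-3 all 8 values lay above 0, with medians of 1.31 and 1.07. AKINBETA1 was at 1.44 in sex1-3 and -1.12 in ptpkis2 with all arrays.

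The direct comparison of ptpkis2 with sex1-3, which asked where the mutants differ and used no wild type array for its fold changes, separated these genotypes in named genes. AT1G73600 was 84.6-fold higher in ptpkis2 (6.40 ± 0.40, n = 3 per genotype, adjusted p = 8.2e-06), and CHIL (5.26 ± 0.72, adjusted p = 0.00096) and GH9B8 (4.43 ± 0.75, adjusted p = 0.0033) were higher by sizes that rest on sex1-3 signals near background and were 4.19 and 3.44 with low signals raised to the 20th percentile. SIS was 22.8-fold lower (-4.51 ± 0.45, adjusted p = 0.00011) and AT3G15450 22.5-fold lower (-4.49 ± 0.18, adjusted p = 2.6e-07). MCCA fell by 2.69 ± 0.21 and IVD by 2.41 ± 0.48 (adjusted p = 3.6e-05 and 0.0083). The carbon starvation list was lower in ptpkis2 than in sex1-3 (median -1.18, 3 of 8 members lower, or 5 when adjusted over the list alone, camera adjusted p = 8.4e-07, adjusted p = 0.0028 with an estimated correlation), and the light harvesting list had a median of 0.00 and 0 of 5 members past the threshold (adjusted p = 0.97). In all, 1291 probe sets were called, 721 higher and 570 lower in ptpkis2, with non-overlapping signals in 45.3% of all tested probe sets. The count was 3970 without wild type replicate 2 and with the filter from the other 11 arrays, and 677 to 785 without 1 of the ptpkis2 or sex1-3 arrays.

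Between sex4-3 and sex1-3, a comparison that shares the sex1-3 arrays with the previous one, the named genes with the largest rises in sex4-3 were CHIL (5.16 ± 0.72, n = 3 per genotype, adjusted p = 0.0035), AT1G13650 (4.62 ± 0.67), AT1G73600 (4.00 ± 0.40), AT5G22460 (3.87 ± 0.73) and GH9B8 (3.68 ± 0.75). With low signals raised to the 20th percentile, CHIL and AT1G13650 were at 4.09 and 4.19, and AT5G22460 and GH9B8 at 2.55 and 2.69 no longer passed. AT1G72060 (-3.06 ± 0.36), AT3G15450 (-2.66 ± 0.18), IVD (-2.45 ± 0.48), SIS (-2.23 ± 0.45) and MGL (-2.22 ± 0.51) were lower in sex4-3. IVD and MGL had adjusted p of 0.021 and 0.045. In all, 332 probe sets were called, 222 higher and 110 lower in sex4-3. The count was 1907 without wild type replicate 2 and 113 to 205 without 1 of the 6 arrays compared.

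Between ptpkis2 and sex4-3, TBL26 was 4.32-fold higher in ptpkis2 (2.11 ± 0.30, n = 3 per genotype, adjusted p = 0.027). AT2G20670 (-1.90 ± 0.23, adjusted p = 0.0082), AT3G15450 (-1.83 ± 0.18, adjusted p = 0.0028), AT2G05540 (-1.63 ± 0.23, adjusted p = 0.027) and AKINBETA1 (-1.14 ± 0.14, adjusted p = 0.0082) were lower in ptpkis2. These were 5 of the 9 probe sets called, 2 higher and 7 lower in ptpkis2. The count was 226 without wild type replicate 2, and 2, 3 or 4 without any array of these genotypes but ptpkis2 replicate 3, where it was again 9.

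**Figure D4:**
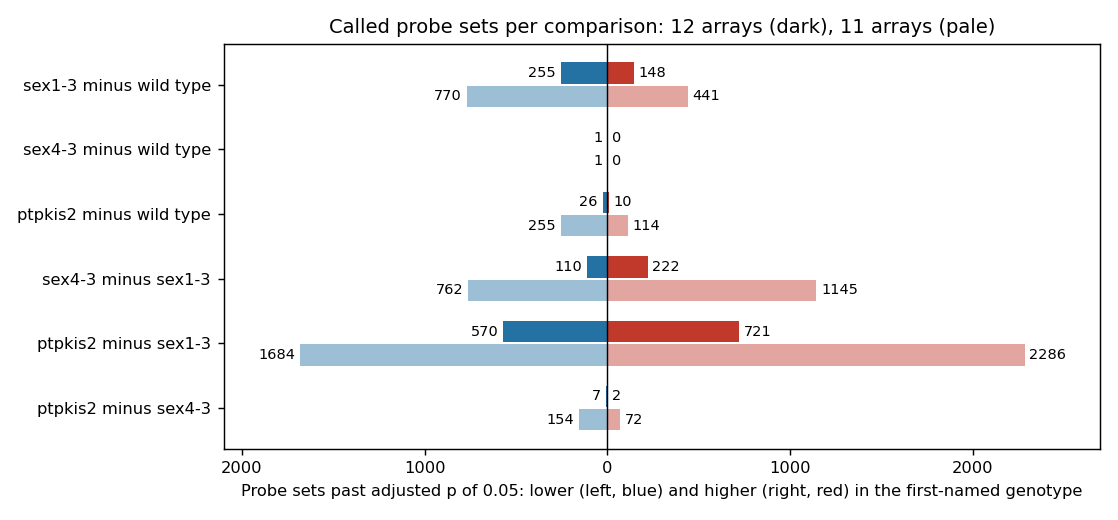
Probe sets called at an adjusted p below 0.05 in each of the 6 comparisons, higher (right, red) or lower (left, blue) in the first-named genotype, from all 12 arrays (dark) and without wild type replicate 2 (pale). The counts rose from 403 to 1211 for sex1-3 minus wild type and from 36 to 369 for ptpkis2 minus wild type, and stayed at 1 for sex4-3 minus wild type.

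No probe set was called in the same direction in all 3 mutants, where independent lists give 3.6e-05. Since sex4-3 had 1 call against wild type, that 0 was nearly fixed in advance and does not show that the mutants share no response. The F-test for any difference of a mutant from wild type called 621 probe sets, and 2783 without wild type replicate 2 and with the filter from the other 11 arrays. It called 228 to 281 without 1 of the sex1-3 arrays and 306 to 325 without 1 of the ptpkis2 arrays. Between sex1-3 and ptpkis2, 14 probe sets were called in both against wild type and all moved in opposite directions: 11 were higher in sex1-3 and lower in ptpkis2, AKINBETA1 among them, where independent lists give 0.282, and 3 were lower in sex1-3 and higher in ptpkis2, where they give 0.187. Leaving out wild type replicate 2 made these counts 60 and 37 (8.24 and 6.43 for independent lists), beside 6 higher and 11 lower in both (3.68 and 14.4). Unchanged groups simulated against the shared wild type arrays gave at most 0 shared calls. Groups without true changes have few calls to share, so that 0 was nearly fixed in advance and is no benchmark for the shared calls.

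Fold changes against wild type correlated across probe sets, which are not independent replicates, at 0.67 between sex1-3 and sex4-3, 0.44 between sex1-3 and ptpkis2 and 0.82 between sex4-3 and ptpkis2. Their covariances were 0.308, 0.216 and 0.308, where unchanged groups sharing the wild type arrays gave a simulated correlation of 0.88 and covariance of 0.338. The simulated replicate 2 held its own noise plus the real deviations of replicate 2 from the other wild type arrays, which already include such noise. It was therefore noisier than the real array, so 0.88 and 0.338 are too high to serve as a benchmark. Between sex1-3 and ptpkis2 the correlation was 0.67 without wild type replicate 1 and 0.69 without replicate 3. The correlations without wild type replicate 2 were 0.28, -0.08 and 0.55, and the covariances were 0.0508, -0.021 and 0.0759 beside simulated values of 0.0685, 0.0686 and 0.0686 (simulated correlation 0.6). With wild type replicates 1 and 3 each used for 1 mutant, so that no array was shared, the covariances, as means of the 2 assignments, were -0.0212, -0.0929 and 0.00399.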

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

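The tests on wild type replicate 2 and on chloroplast transcripts, and the covariance with a different wild type array for each mutant, were chosen after the results were seen, and for chloroplast transcripts the bound was raised from 2 to 2.36 SE after the values were known. The other tests on the opposite movement of sex1-3 and ptpkis2 and those on other splits of the arrays were written before their values were seen.

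Wild type replicate 2 stood apart because its spike-in probe sets, which none of the comparisons use, had a median ratio of 23.3 to the other arrays. An array of another genotype under a wrong label cannot be told apart, since its highest correlation with any array of 0.604 would be low for so noisy an array of any genotype, and probe sets called in the other 11 arrays gave mixed positions between mutant (0) and wild type (1), with medians of 1.3 and 0.52 for those higher and lower in sex1-3 and 0.97 and 0.3 for ptpkis2. Too little labelled plant RNA may account for the array, since spike-ins are added in a fixed amount. Degraded RNA is a further candidate explanation, since 5 of 6 control pairs had a 3′ to 5′ ratio above all other arrays. The pairs cover only actin, GAPDH and ubiquitin, and the remaining pair, of actin, lay below all other arrays (5.22 against 7.2 to 13.1). The 2 explanations, too little labelled RNA and degraded RNA, can act together and were not separated. The design gives this array no genotype of its own, so no biological explanation was tested.

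The carbon starvation list shifted up in sex1-3 and not in ptpkis2, and the direct test of the difference gave p = 0.0014 with an estimated correlation (median -1.18 for ptpkis2 minus sex1-3). A difference in signal distribution between arrays was argued against by quantile normalization of the 11 arrays, after which the list's median difference was -1.25 (p = 0.0043 with an estimated correlation). Noise of the shared wild type arrays raises the covariance of the fold changes. For the opposite movement across probe sets such noise was argued against, since that covariance was -0.021 without wild type replicate 2. With a different wild type array for each mutant, the 2 assignments gave -0.126 and -0.0596. Leaving out 1 array of each mutant gave -0.133 to -0.0464 in 18 of 18 subsets. These subsets overlap and all use wild type replicates 1 and 3, so they are not independent. For the list itself the side of wild type on which ptpkis2 lies stays open, since it did not pass there with an estimated correlation (adjusted p = 0.23). The genotype stays open as an untested explanation, and the labels name no tray or harvest order, so a difference in handling was not tested.

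Transcripts of the chloroplast genome, an added list of 69 genes, had a median of -0.98 in sex1-3 against wild type, with 5 that fell, or 12 without wild type replicate 2 (camera adjusted p = 1.1e-08 with 12 arrays, but adjusted p = 0.68 with an estimated correlation). Their high signal on wild type replicate 2 could account for most of the median shift, since without that array the list medians per array differed by -0.37 ± 0.18, or -2.12 SE, between the bounds set for the 2 outcomes. What remains does not come from that array, but it lies close to the bound of 2.36 SE. A difference in signal distribution between arrays stays open too, since quantile normalization of the 11 arrays took the shift from short of that bound to just past it (-0.38 ± 0.16, or -2.40 SE). The genotype stays open as an untested explanation.

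Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For the calls of each of the 6 comparisons, 1 of 10 splits, the real one, gave as many: the counts were 403, 1, 36, 332, 1291 and 9, and the highest of the other splits gave 0 in each. For the lists called, sex1-3 had 1 of 10 (real value 1, highest other 0), and sex4-3 and ptpkis2 had 10 of 10, since the real value and the highest other were both 0. Regrouping all 12 arrays gave as many calls in the F-test in 1 of 100 draws, the real grouping, with 621 calls against at most 358. A random assignment of these arrays to genotypes thus did not reach that count. Since the arrays of a genotype may be technical, the test cannot exclude chance differences between plants or pools. For calls in the same direction in all 3 mutants, 100 of 100 regroupings gave as many, since the real count was 0 and the highest other 0. Any regrouping reaches a count of 0, so that test decides nothing.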

How the results depend on the processing

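Array weights and the settings that drop wild type replicate 2 and take filter, floor, pseudocount, block or quantiles from the other 11 arrays were chosen after seeing the data, and the others before. Of 70 values for named genes and the call in sex4-3, 61 passed in all 12 arrays and 0 of these turned direction under any alternative. All 61 passed with array weights, with robust eBayes and in the 5 settings from 11 arrays, 58 with the floor, 58 with the pseudocount, 54 with no filter, 49 without a trend, 45 after quantile normalization, 34 after median centring, 25 with the 2 genotypes compared alone and 43 of the 43 left with the lowest 60% out. With 1 array left out, among the named calls that use its genotype, 30 of 36 passed without wild type replicate 1 or 3, and 36 of 36 without replicate 2. Leaving out 1 sex1-3 array kept 31 of 42, 1 sex4-3 array 7 to 9 of 16, and 1 ptpkis2 array 14 to 16 of 28. In sex1-3 the carbon starvation list passed camera under all alternatives. Signals near background limit the falls in sex1-3. Median centring moved the median fold change of all probe sets by 0.54 (sex1-3), 0.41 (sex4-3) and 0.31 (ptpkis2) against wild type, and by -0.24 for ptpkis2 minus sex1-3 and -0.14 for sex4-3 minus sex1-3; quantile normalization moved the first 3 by 0.17, 0.13 and 0.11. Under centring, 61.6% of calls were higher in sex1-3 than in wild type, where the signals as deposited gave 36.7%, and 40% against 55.8% were higher in ptpkis2 than in sex1-3; for ptpkis2 minus wild type the 1 call was higher, against 27.8%. Where a value differs below, the cause was not tested unless arrays or probe sets were removed.

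Counts are given in the order sex1-3, sex4-3 and ptpkis2 against wild type, then sex4-3 minus sex1-3, ptpkis2 minus sex1-3 and ptpkis2 minus sex4-3, for which all 12 arrays gave 403, 1, 36, 332, 1291 and 9. Quantile normalization gave 207, 0, 32, 222, 900 and 14, and median centring 86, 0, 1, 57, 470 and 0, with 155 in the F-test for any genotype difference. The unfiltered table gave 18 for ptpkis2 minus wild type, leaving out the lowest 60% gave 59 there and 17 for ptpkis2 minus sex4-3, the pseudocount gave 16 for the latter, and eBayes without a trend gave 14 for ptpkis2 minus wild type. Fits of the 2 genotypes compared alone gave 0, 0, 0, 1461, 4257 and 205. Array weights gave 2015, 24, 799, 2819, 4627 and 993, with 4073 in the F-test and 9 probe sets shared by all 3 mutants. Without wild type replicate 2 the counts were 1211, 1, 369, 1907, 3970 and 226 with the filter of the 11 arrays (F-test 2783), 1242, 1, 380, 1943, 3987 and 229 with a floor (2819), 1258, 1, 383, 1946, 4011 and 230 with a pseudocount (2856), and 1124, 1, 421, 1804, 3830 and 257 after quantile normalization (2723). Leaving out 1 array at a time of the 2 genotypes compared gave 157 to 1207, 1 throughout, 6 to 367, 113 to 205, 677 to 785 and 2 to 9, and leaving out any 1 array gave 228 to 2774 in the F-test, where all 12 arrays gave 621.

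The replicate numbers showed no clear pairing: deviations of same-number arrays from their group means correlated at -0.069 to 0.114 (median -0.013). In 2 of 18 pairs r exceeded 0.1, and 3 of 12 arrays correlated best with their own number. Deviations of the wild type arrays were dominated by replicate 2, so the pairs with wild type tell little. With the replicate block the counts were 305, 1, 12, 261, 1129 and 9, with 505 for any genotype difference, 0 probe sets shared by all 3 mutants and correlations of 0.67, 0.44 and 0.82, and 1, 0 and 0 fixed lists passed in sex1-3, sex4-3 and ptpkis2. Without wild type replicate 2 the block gave 1214, 1, 342, 2075, 4054 and 233, with 2823 in the F-test. Of the 61 named calls, 11 did not pass with the block.

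The correlation of fold changes between sex1-3 and sex4-3 was 0.39 with array weights and, without wild type replicate 2, 0.28 with the filter, 0.28 with a floor, 0.27 with a pseudocount, 0.31 with the block and 0.28 after quantile normalization (0.28 to 0.82 leaving out 1 array). For sex1-3 and ptpkis2 these were 0.04, then -0.08, -0.08, -0.11, -0.04 and -0.08 (-0.08 to 0.69), a reversal of the 0.44 from all arrays. For sex4-3 and ptpkis2 they were 0.54, then 0.55, 0.55, 0.56, 0.57 and 0.54 (0.55 to 0.91), and 0.71 with no filter; quantile normalization of all 12 arrays gave 0.78, 0.63 and 0.89. In ptpkis2 against wild type 1 of 2 fixed lists, carbon starvation, passed with fry, with the lowest 60% left out, with array weights and in each setting without wild type replicate 2, where camera on all arrays gave 0 (0 to 1 leaving out 1 array).

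Of the 70 values for named genes and the call in sex4-3, those that turned direction all belonged to uncalled starch degradation genes. Other values given here also turned without wild type replicate 2, such as SIR in sex1-3 (0.11 to -0.74). Median centring gave PWD at 0.25, 0.01 and 0.25 in sex1-3, sex4-3 and ptpkis2, and PWD in ptpkis2 was 0.07 with array weights and -0.17 to 0.05 leaving out 1 array. Without wild type replicate 2, DPE1 in sex4-3 was 0.03 with the filter (-1.14 to 0.03 leaving out 1 array), 0.03 with a floor, 0.04 with a pseudocount, 0.16 with the block and 0.08 after quantile normalization, and DPE1 in ptpkis2 was 0.07 with the block. AMY1 in ptpkis2 was 0.00 with a pseudocount and 0.28 with the block, and AMY1 in sex1-3 was 0.25 with the block and 0.05 after quantile normalization.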

Other observations

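The genes and lists in this part were chosen after the data were examined, apart from the lists' members, which were written before any fold change was looked at. Between ptpkis2 and sex1-3, 7 of 21 added lists passed camera, 0 of 21 passed with an estimated correlation, and 8 of 21 passed fry. Cytosolic ribosomal protein genes were higher in ptpkis2, with 29 of 103 members that rose and a median of 0.61 (adjusted p = 3e-14, or adjusted p = 0.22 with an estimated correlation). Tubulin genes had 4 of 6 members that rose in ptpkis2, such as TUB9 (1.31 ± 0.19, adjusted p = 0.0012) and TUB7 (1.23 ± 0.22, adjusted p = 0.0048), and the list had an adjusted p of 0.0061, or 0.19 with an estimated correlation. Chloroplast genome transcripts had 8 of 69 that rose (median 0.83, adjusted p = 2.3e-06, or 0.47 with an estimated correlation). Autophagy genes had 11 of 11 values below 0 and 1 that fell, ATG8F (-1.01 ± 0.16, adjusted p = 0.002; list median -0.60, adjusted p = 0.00017, or 0.19 with an estimated correlation). Genes of branched-chain amino acid and lysine breakdown had 3 of 9 that fell (median -0.81, adjusted p = 0.00066, or 0.12 with an estimated correlation). That list shares members with the carbon starvation list, IVD and MCCA among them. Expansins and xyloglucan transglycosylases had 3 of 12 that rose (median 1.08, adjusted p = 0.0061, or 0.21 with an estimated correlation), and serine carboxypeptidase-like genes 3 of 15 (median 0.85, adjusted p = 0.0054, or 0.19 with an estimated correlation). Without wild type replicate 2 more members passed: 64 ribosomal protein, 5 tubulin, 35 chloroplast, 7 expansin or xyloglucan transglycosylase and 8 serine carboxypeptidase-like genes rose, and 7 autophagy and 5 amino acid breakdown genes fell, while 1 tubulin and 1 serine carboxypeptidase-like gene fell. The medians of these 7 lists kept their sign under all 22 alternatives, or 21 for expansins.

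Against wild type, 5 added lists passed camera in sex1-3, 3 in sex4-3 and 2 in ptpkis2, 0 passed with an estimated correlation, and fry gave 5, 0 and 0. In sex1-3, branched-chain amino acid and lysine breakdown had 3 of 9 members that rose (median 1.19, adjusted p = 0.0018, or 0.4 with an estimated correlation), with ALDH6B2, an aldehyde dehydrogenase of valine breakdown, at 1.28 ± 0.24 (adjusted p = 0.016) beside IVD and MCCA. IVD and MCCA also belong to the carbon starvation list, so the results of these lists are not independent. Lower in sex1-3 were the lists of expansins and xyloglucan transglycosylases (median -0.89, 1 of 12 fell, adjusted p = 0.021, or 0.68 with an estimated correlation), mitochondrial genome transcripts (-1.17, 0 of 8, adjusted p = 0.021, or 0.81) and serine carboxypeptidase-like genes (-0.58, 2 of 15 fell, adjusted p = 0.023, or 0.67). The first 2 of these did not pass without wild type replicate 2, with medians of -0.70 and -0.43. In sex4-3 the lists were ribosomal proteins (median 0.31, adjusted p = 1.5e-09, or 0.68 with an estimated correlation), mitochondrial genome transcripts (-1.18, adjusted p = 0.0012, or 0.68) and chloroplast genome transcripts (-0.41, adjusted p = 0.0014, or 0.96), each with 0 members past the threshold. Without wild type replicate 2 the chloroplast list reversed and passed camera as higher (median 0.14), as it did in ptpkis2 (median 0.30), and the mitochondrial list, at -0.41, did not pass. With an estimated correlation the chloroplast list then passed in neither mutant (camera adjusted p = 0.85 in sex4-3). In ptpkis2, ribosomal protein genes had a median of 0.43 with 1 of 103 that rose (adjusted p = 5.7e-13, or 0.68 with an estimated correlation). Autophagy genes had a median of -0.28 with 0 of 11 past the threshold (adjusted p = 0.048, or 0.68). The autophagy median turned to 0.02 under median centring, which also moved the median of all tested probe sets from 0.05 to 0.36.

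Some further genes, chosen after their values were seen, were looked at in sex1-3 against wild type. QQS, named for its effect on leaf starch, fell by 2.82 ± 0.30 (adjusted p = 0.00061) and had a value of -0.93 ± 0.30 in ptpkis2 (adjusted p = 0.27), which passed without wild type replicate 2 at -1.26. The sugar transporters SWEET17 and SWEET1 fell by 2.35 ± 0.26 and 1.14 ± 0.19 (adjusted p = 0.00093 and 0.009), and their list passed fry (adjusted p = 0.001) but not camera (adjusted p = 0.087). The cellulase family members GH9C2 and GH9B7 fell by 2.74 ± 0.47 and 1.85 ± 0.26 (adjusted p = 0.01 and 0.0032). BCAT4, an aminotransferase of glucosinolate synthesis from methionine, fell by 2.95 ± 0.53 (adjusted p = 0.013), the glutathione transferase GSTU20 by 2.84 ± 0.34 (adjusted p = 0.0013), and the transcription factor MYC4 by 1.28 ± 0.26 (adjusted p = 0.022). The N-methyltransferase PMEAMT and the ATP sulfurylase APS3 fell by 2.31 ± 0.34 and 1.27 ± 0.27 (adjusted p = 0.0042 and 0.032). The others looked at with them, AOP1 (-1.51 ± 0.51), UGT74B1 (-0.12 ± 0.79), GTR1 (0.08 ± 0.37), GTR2 (0.54 ± 0.62) and SIR (0.11 ± 0.52), did not pass (adjusted p = 0.14, 0.94, 0.9, 0.6 and 0.91), and without wild type replicate 2 UGT74B1 (-1.34) and SIR (-0.74) passed and AOP1 (-0.79), GTR1 (-0.38) and GTR2 (-0.33) did not. COR27, a cold-regulated gene of the circadian system, rose by 2.21 ± 0.32 (adjusted p = 0.0042).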
